A study of Mus musculus with 8 samples.

How the data were processed

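RNA was measured in 8 samples of sorted mouse cells, 4 from chimeras that carried wild-type bone marrow (Psgl1 +/+) and 4 from chimeras that carried Selplg knockout bone marrow (Psgl1 -/-). Selplg is the gene symbol of PSGL-1. Groups and replicate numbers were taken from the labels, in which the wild-type samples are numbered 1 to 4 and the knockout samples 5 to 8. The labels describe bone marrow chimeras but do not say how many animals contributed to each sample, so p-values measure only the spread between these samples, which may in part be technical.

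Per the labels' protocols, total RNA was amplified and labelled with cyanine 3 in a low-input kit that used random primers for the first strand, with a cRNA yield of 12.5 to 14.4 µg and a dye incorporation of 35.5 to 38.1 pmol per µg. Per the file headers, each sample was hybridised to 1 array of an Agilent custom design in a single colour and read with Agilent Feature Extraction. The deposited scanner files give the brightness of each spot as an intensity on a linear scale, which Feature Extraction had corrected for background and for spatial trends within the array but not between arrays, per the file headers. The file headers name mouse build mm9. The authors also deposited a value table of 59448 rows, whose scale is not given in the sources used here. Set against the scanner files, its columns were linear intensities with identical sorted values, which is the outcome of quantile normalization, and each column had a median of 132.9. On the log2 scale each column correlated with its own array at 0.9975 or more and with any other array at 0.8091 or less. Both kinds of file held intensities, and the value table was used only as an alternative.

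All 8 arrays lay on 1 slide and were read in 1 scan, so neither slide nor scan could be a batch. The slide has 2 rows, each of which held 2 wild-type and 2 knockout arrays. Slide columns 1 and 2 held wild-type arrays and columns 3 and 4 held knockout arrays, so slide column and group cannot be told apart.

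Each array had 62912 spots, of which 61473 were gene spots. Control spots (1439) were left out, as were spots marked as outliers (25 to 149 per array), and no spot was saturated. Spots of a probe were averaged. Of 60273 probes, 31064 were named through a RefSeq accession, 8935 through a symbol that the files and the reference table share and 420 through an older symbol, which together is 67.1% of probes. The reference table is of assembly GRCm38.p6, which is not the build of the files, and served only for names and for which genes lie beside each other. A further 12259 probes kept an unmatched accession, 5498 another identifier and 2097 a symbol not in the table. The probes carried 47242 distinct names.

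For the tests, the 75th percentile of the processed signal of each array was subtracted on the log2 scale, and each gene was represented by the probe with the highest mean over all 8 arrays. Genes were kept where that probe was well above background on at least 4 of 8 arrays, which left 42312 genes, 25657 of them with a gene symbol, while 186 probes lacked a value on some array. Group differences (knockout minus wild-type) were fitted with limma (version 3.58.1, lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a two-sided threshold of 0.05. For a gene below background on every array of a group, the fold is a bound, taken against the higher of the lowest signal well above background and the probe's own signal on each array. The number of arrays limits the precision of all values.

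Gene lists were tested with camera, which compares the genes of a list with all other tested genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 44 lists of function (24) or cell type (20). Of 1119 list entries, 1099 were on the array, and Selplg was left out of the list tests. Each list was also tested with a correlation estimated from its genes, and with fry, which asks whether the genes of a list move on balance in a single direction and, in its mixed form, whether they change in either direction. A list of the neighbours of Selplg on chromosome 5 and a list of 5 sex-linked genes served as checks. The former held 32 genes on chromosome 5, after leaving out 2 (Pwp1 and Prdm4) that lie on chromosome 10 in the reference. Sex-linked genes were compared by exact permutation tests. Files were read with the R package data.table (version 1.17.8) and with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

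The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where said otherwise. The rule took Selplg, the 12 genes with the largest difference in each direction among genes with a symbol that pass the threshold with groups that do not overlap, filled by the smallest unadjusted p where fewer pass, up to 4 members of each called list, up to 2 of each other list, and the chromosome 5 and sex-linked lists in full. For brevity, values are given for 2 members of each called list and those of its 4 at an unadjusted p under 0.05, 1 member of each other list and the chromosome 5 genes at an unadjusted p under 0.05, a narrowing made after the values were seen. The other chromosome 5 genes are shown in a plot. Some genes picked by the rule are not reported here, and no others took their place, while all fits, lists and counts of tested genes include them. The genes of the sort markers (Itgam, Ptprc, Ly6g, Cd3d, Cd3e and Cd3g) were added after the values were seen.

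The alternatives named at that stage were quantile normalization, scaling to the array median, normexp background correction (offset 50) with quantile normalization, the deposited value table, no filter on dim probes, a filter at all 8 arrays, eBayes with trend and robust settings, array weights, the slide row as a block, the mean over all probes of a gene, an adjusted threshold of 0.1, a least log2 difference of 1, lists without shared genes, and leaving out each array in turn. A further 4 were chosen after seeing the data: only probes named through a RefSeq accession, the brighter part of the tested genes, cyclic loess between arrays, and leaving out knockout replicates 7 and 8 together. Knockout replicates 7 and 8 were the highest arrays on the first principal component, and no wild-type array was left out with them. The tests were checked on simulated data made from the spread of the 42312 genes of the knockout against wild-type comparison. Of 50 genes changed by each size, 24% were recovered at a log2 change of 2, 52% at 4 and 82% at both 6 and 8, with 6 wrong calls. With no change simulated, 5% of genes had an unadjusted p under 0.05 and 0 genes and 0 lists were called. Genes were simulated independently of each other, with 200 changed at once. The shares recovered therefore need not hold for these arrays, where 1 gene was called. The 0 genes and 0 lists do not show how limma and camera behave where genes vary together. Of 35 splits of the real arrays into 4 and 4, 20 gave at least 1 gene past the threshold, the real split included.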

Results

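The series profiled donor-derived myeloid cells from the mouse brain after an experimental stroke. Bone marrow that carried the red fluorescent protein DsRed, from wild-type or Selplg knockout donors, was transplanted into wild-type mice. Selplg encodes PSGL-1, a glycoprotein on leukocytes that binds selectins and mediates rolling on the vessel wall. The middle cerebral artery was occluded for 30 min, which starves part of the brain of blood, and the tissue was taken 7 days after reperfusion. Live DsRed-positive, CD11b-positive cells with high CD45, without the neutrophil marker Ly6G and the T cell marker CD3, were sorted. Their RNA was hybridised to 8 single-colour arrays, 4 labelled wild-type (replicates 1 to 4) and 4 labelled knockout (replicates 5 to 8). The comparison asks how the RNA of these cells differs with the PSGL-1 genotype of the donor.

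Of the gene spots of each array, 81.6%, 86.8%, 76.1% and 86.2% were well above background on wild-type replicates 1 to 4, and 81.2%, 88.2%, 76.2% and 87.6% on knockout replicates 5 to 8. The 75th percentile of the processed signal was 691.1, 748.6, 611.0 and 525.8 on the wild-type arrays and 859.4, 868.8, 833.3 and 958.8 on the knockout arrays, so that every knockout array was above every wild-type array in this measure before scaling. The median processed signal did not separate the groups in this way, at 126.5 on knockout replicate 7 against 139.6 and 143.9 on wild-type replicates 1 and 2. After scaling, arrays of a group correlated at 0.75 to 0.79 over all tested genes (median 0.768) and arrays of different groups at 0.72 to 0.79 (median 0.767).

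Selplg signal differed by less than the spread between arrays, and a single gene, the zinc transporter gene Slc39a6, was higher in the knockout arrays past the adjusted threshold, by 26.4-fold (log2 difference 4.72, SE 0.29, n = 4 per group, adjusted p = 0.0125). At least 1 gene past the threshold was also found in 20 of the 35 splits of the 8 arrays into 4 and 4, the real split included. Chance therefore cannot be excluded for this gene. By the preset-correlation test of gene lists, 18 of 44 lists lay higher relative to the other genes in the knockout arrays, led by oxidative phosphorylation and followed by type I interferon response, iron and oxidative stress, lipid uptake and efflux, and hypoxia response. Markers of border-associated macrophages and Ly6C-high monocytes were the cell type lists among them. The groups overlapped in the mean signal of each of these 18 lists, and no list passed when the correlation between its genes was estimated (lowest adjusted p = 0.28 with an estimated correlation).

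Selplg was read by 1 probe (accession NM_009151.3, 46 bases, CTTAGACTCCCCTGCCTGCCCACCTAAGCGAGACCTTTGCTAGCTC), which was well above background on all 8 arrays. Its log2 signal after scaling was 13.79, 12.68, 13.05 and 15.74 on wild-type replicates 1 to 4 and 13.25, 13.45, 13.16 and 12.88 on knockout replicates 5 to 8. The means were 13.81 ± 1.36 (SD, n = 4) and 13.18 ± 0.24 (SD, n = 4), a difference of -0.63 (SE 0.64, limma adjusted p = 0.684). Without wild-type replicate 4 the difference was 0.01. The probe sequence has a stop codon in all 6 reading frames of both strands, so it cannot lie wholly within coding sequence, and which part of the gene the knockout lacks is not given in the sources used here. The probe therefore checks nothing about the labels, and the directions below rest on the labels.

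Slc39a6, which encodes a zinc importer of the plasma membrane, had a log2 signal of 5.76 ± 0.33 (SD, n = 4) in the arrays labelled wild-type and 10.48 ± 0.33 (SD, n = 4) in those labelled knockout, and all 4 knockout arrays lay above all 4 wild-type arrays. The gene was read by 1 probe, so no other probe could be set beside it. Over 23 settings its difference ranged from 3.8, with normexp, to 5.0, and its adjusted p from 0.00482 to 0.0843. The call was lost without wild-type replicate 1 (difference 4.64, adjusted p = 0.0621), without knockout replicate 7 (4.63, adjusted p = 0.0843) and without knockout replicates 7 and 8 together (4.70, adjusted p = 0.0734 for gene Slc39a6). In these settings the difference stayed near 4.72 while fewer arrays were tested. No gene was lower in the knockout arrays past the threshold by limma, the only tool run over all genes, while 688 genes were higher and 3883 lower at an unadjusted p under 0.05. The count of changed genes was 0, 4, 10 and 4 without wild-type replicates 1, 2, 3 and 4, and 3, 10, 0 and 2 without knockout replicates 5, 6, 7 and 8. In the settings with 0 changed genes, 3438 genes (without wild-type replicate 1) and 2770 (without knockout replicate 7) had an unadjusted p under 0.05.

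The other 10 named genes with positive differences did not pass. For each, all 4 knockout arrays lay above all 4 wild-type arrays, which picking by the smallest p favours. Of all tested genes, 11.4% had groups without overlap in either direction. Slc20a1, a sodium-dependent phosphate transporter, had a difference of 5.89 (SE 0.53) and Ube2q2, a ubiquitin-conjugating enzyme, of 6.08 (SE 0.55), each with an adjusted p of 0.052. Ncbp2, a subunit of the nuclear cap-binding complex, had the same adjusted p and was not well above background on any wild-type array. This gives at least 92.9-fold in the main setting only, since its log2 difference ranged from 4.55 to 8.23 over 21 settings. Ssb, the La protein that binds RNA polymerase III transcripts, differed by 5.44 (SE 0.55) and Ube2f, an enzyme that conjugates NEDD8, by 2.60 (SE 0.26), both at an adjusted p of 0.06. The endoplasmic reticulum protein Erlin2 differed by 6.36 (SE 0.72, adjusted p = 0.0953) and the kinase Dyrk1a by 5.84 (SE 0.68, adjusted p = 0.0994). Ndufv1 of respiratory complex I (5.60), the phosphatidylserine synthase Ptdss1 (4.53) and the actin-binding Actn4 (4.36) had adjusted p-values of 0.164, 0.216 and 0.221. Dyrk1a and Ndufv1 were each well above background on 1 of 4 wild-type arrays, so the size of their differences is uncertain. Over 21 settings it ranged from 3.02 to 6.40 for Dyrk1a and from 3.46 to 6.03 for Ndufv1. At an adjusted p under 0.1 there were 14 genes, 11 higher and 3 lower. Ncbp2 passed without knockout replicate 5 (adjusted p = 0.0365, range 0.0275 to 0.167 over all settings), and without knockout replicate 6 so did Ube2q2 (adjusted p = 0.0112, range 0.0112 to 0.144) and Erlin2 (adjusted p = 0.0154, range 0.0154 to 0.245). Other settings with all arrays also brought calls. With probes named through RefSeq the adjusted p was 0.0275 for gene Slc20a1, gene Ube2q2 and gene Ncbp2, 0.0416 for gene Ssb and 0.0425 for gene Ube2f. Among the brighter genes it was 0.0283 for Slc20a1 and Ube2q2, 0.0351 for Ssb and 0.0329 for Ube2f. With the filter at all 8 arrays it was 0.0485 for Ube2q2, Ssb and Ube2f, after cyclic loess 0.04 for Slc20a1 and Ube2f, and in the mean over all probes 0.0466 for Ube2q2 and Ncbp2.

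None of the 12 named genes with negative differences passed either. Klc3, a kinesin light chain, had the smallest adjusted p of them (0.06), with a log2 signal of 7.99 ± 0.20 (SD, n = 4) in the wild-type arrays and 5.65 ± 0.17 (SD, n = 4) in the knockout arrays. The difference was -2.34 (SE 0.23), and gene Klc3 passed with probes named through RefSeq (adjusted p = 0.0416) and with the filter at all 8 arrays (adjusted p = 0.0485). Fam169a (-4.39), Trim34b of the tripartite motif family (-3.98), whose probe also lists Trim34a, and the zinc finger gene Zfp945 (-1.91) had adjusted p-values of 0.21, 0.221 and 0.313. The phenylalanyl-tRNA synthetase subunit Farsb (-3.69) and the olfactory receptor Olfr1349 (-1.57) had 0.406 and 0.443. The dynein adaptor Bicd2 (-1.31), the prefoldin-like Uri1 (-4.05), the kallikrein Klk4 (-1.97), the microRNA gene Mir7025 (-1.28), the cannabinoid receptor Cnr1 (-1.85) and the potassium channel subunit Kcne4 (-1.56) shared an adjusted p of 0.459. Olfr1349, Cnr1 and Kcne4 were each well above background on 2 of 4 knockout arrays, and with normexp the differences were -0.26 for gene Olfr1349, -0.34 for gene Cnr1 and -0.36 for gene Kcne4, so their size depends on the background correction. The same limit applies to genes given further below, of which Acat1, Kif23 and Cpa3 were well above background on 2 of 4 knockout arrays, Ndufs1 and Maf on 2 of 4 wild-type arrays and Ddx3y on 1 of 4 wild-type arrays. Among these 23 genes, 5 had other tested probes, and 2 of those 8 probes had a difference of the same sign as the probe used. The other probe gave -0.50 for Slc20a1, -0.75 for Actn4 and 1.04 for Zfp945, the other 3 of Ube2f gave -0.70 to -0.36, and the other 2 of Farsb gave -3.23 and -0.69. Over all 99 genes given with values in these results, 27 had other tested probes, and 17 of those 40 probes had the same sign as the probe used.

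**Figure D1:**
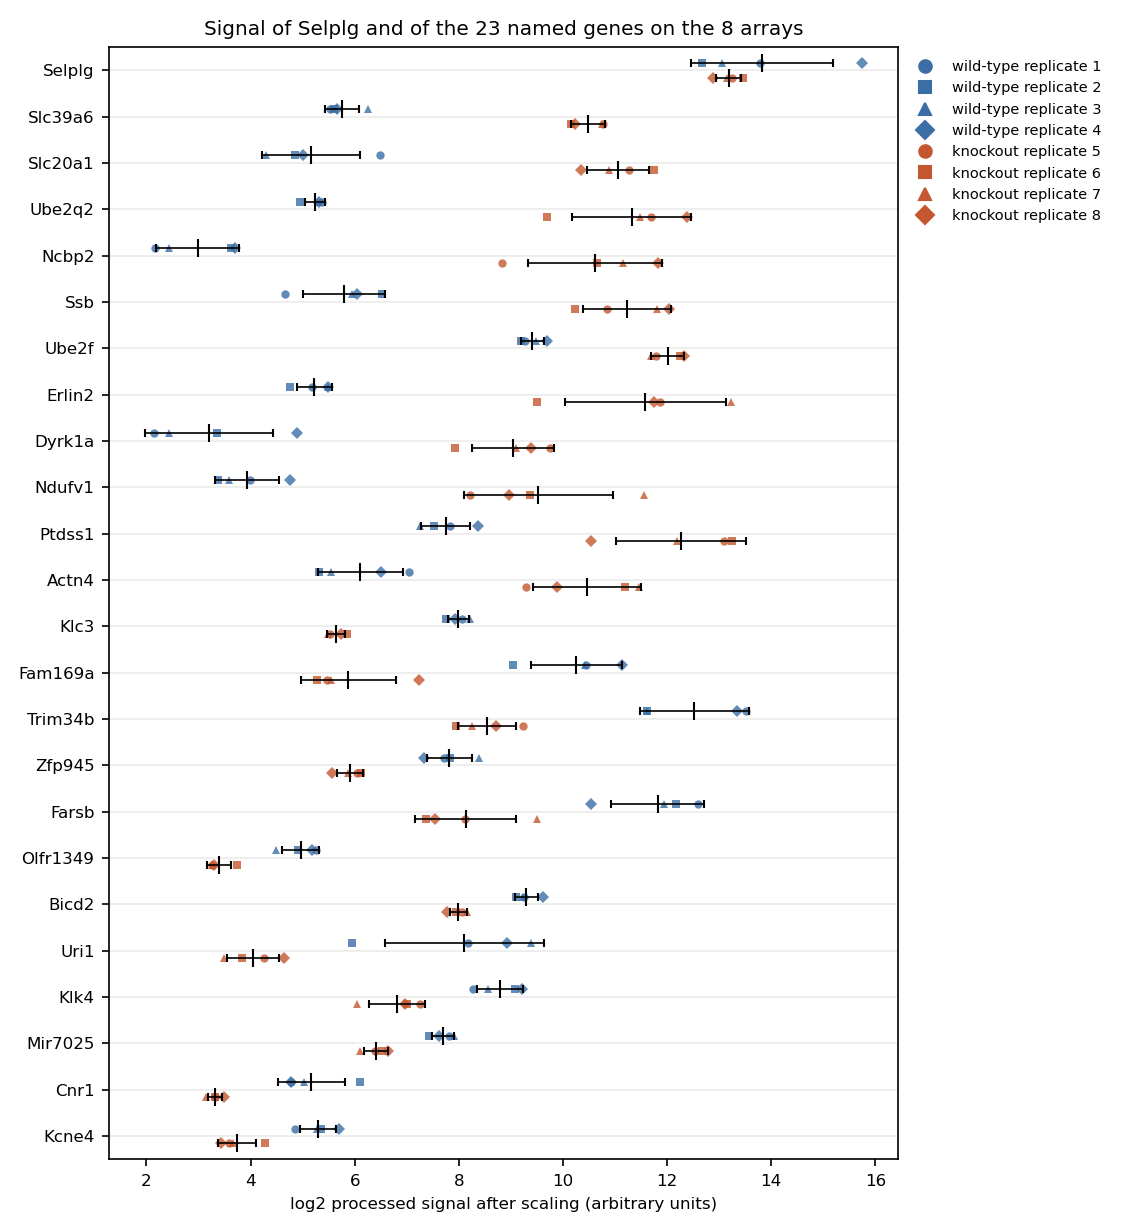
Log2 processed signal after scaling (x axis, arbitrary units) of Selplg and 23 genes with the largest or best-ranked differences, with 1 point per array (blue wild-type, orange knockout) and black bars at the mean ± SD of 4 arrays. The groups do not overlap for the 23 genes, of which Slc39a6 alone passed the adjusted threshold (wild-type 5.76, knockout 10.48), and they overlap for Selplg.

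Over all 42312 tested genes the median difference was -0.33, and 4571 genes (10.8%) had an unadjusted p under 0.05. Without overlap between the groups were 11.4% of genes, 275 higher and 4550 lower, against 2.86% by chance. The shift depended on the scaling: the median difference was -0.17 after quantile normalization, -0.18 after scaling to the array median, -0.11 with normexp and quantile normalization, -0.16 in the deposited value table and -0.01 after cyclic loess. The split at an unadjusted p under 0.05 moved with it, from 688 higher and 3883 lower to 896 and 1891 after quantile normalization, 873 and 1846 after scaling to the array median, 819 and 1970 with normexp, 917 and 1855 in the value table, and 1247 and 797 after cyclic loess. The 4571 genes became 2770 without knockout replicate 7 and 2662 without knockout replicate 8, and the 3883 lower genes became 2005 and 1994 without knockout replicates 7 and 8 and 2543 without wild-type replicate 4. Differences of single genes below are given as measured, next to this shift of -0.33, and camera compares each list with the other genes.

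The 18 called lists, 16 of function and 2 of cell type, held 461 genes, of which 287 had a positive and 174 a negative difference. None of the 461 passed the limma threshold over all genes, while 19 were higher and 14 lower at an unadjusted p under 0.05. By estimated correlation 0 lists passed and 6 had an unadjusted p under 0.05. A higher correlation does not account for every loss. For hypoxia response the estimate was -0.002, below the preset 0.01, yet the unadjusted camera p rose from 0.000377 to 0.00803. The 2 forms of camera thus differ in more than the correlation. By fry 0 lists passed (lowest adjusted p = 0.29), 5 had an unadjusted p under 0.05 and 7 passed in its mixed form. Those 5 lists (conventional dendritic cells 2, mature migratory dendritic cells, T cells, basophils and mast cells, and neurons) all pointed down by fry, and none is among the 18. Of the 7 lists in mixed form, 1, selectin ligand glycosylation, is among the 18. Leaving out wild-type replicates 1, 2, 3 and 4 gave 8, 9, 20 and 14 called lists, and leaving out knockout replicates 5, 6, 7 and 8 gave 20, 20, 1 and 10. The list still called without knockout replicate 7 was oxidative phosphorylation, and without knockout replicates 7 and 8 together 0 lists passed by camera, 1 with an unadjusted p under 0.05. Knockout replicate 7 was the highest of the 8 arrays in 14 of the 18 lists. Leaving it out therefore favours the loss of these calls. Without knockout replicates 7 and 8 together the knockout group was also smaller, so that setting does not show why the calls were lost.

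Of the 26 settings, the one of the main results included, 11 of the 18 lists were called in 17 to 23. The 26 include the tests with an estimated correlation and with fry, which compares a list with 0 and not with other genes. Ranges over all settings below therefore pool unlike tests. For some lists the highest adjusted p is that of fry, as for lysosome (0.954). The other 7 were called in 13 (list Ly6C-high monocytes), 12 (list border-associated macrophages), 11 (list phagocytosis and scavenging), 10 (list alternative activation and repair and list complement and Fc receptors), 8 (list selectin ligand glycosylation) and 5 (list inflammatory activation). Other scalings, 1 of them with another background correction, ended some of these calls. After quantile normalization the adjusted p was 0.0973 for list selectin ligand glycosylation, 0.0808 for list inflammatory activation, 0.0526 for list alternative activation and repair and 0.0507 for list border-associated macrophages. The value table ended the same 4 calls (0.0968, 0.0767, 0.0541 and 0.0508 in that order). Normexp background correction with quantile normalization ended the first 3 of these calls (0.105, 0.0977 and 0.0612) and that of list phagocytosis and scavenging (0.0668). Quantile normalization, the value table and normexp each added 1 call, list heat shock and unfolded protein response. Scaling to the array median ended all 7, with an adjusted p of 0.0611 to 0.0687. Cyclic loess ended all 7 and that of list cell cycle, with an adjusted p of 0.085 to 0.148.

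Genes of energy metabolism and oxygen supply were among the lists that lay higher. Of 42 oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, 34 had a positive and 8 a negative difference (camera adjusted p = 1.68e-07; adjusted p = 0.278 with an estimated correlation). The mean of the list was 8.63, 9.34, 9.85 and 9.92 on wild-type replicates 1 to 4 and 9.65, 9.78, 11.38 and 10.80 on knockout replicates 5 to 8. The complex I genes Ndufv1 and Ndufs1 differed by 5.60 and 4.71 (adjusted p = 0.164 and 0.459), Uqcrc2 of complex III differed by 4.52 (adjusted p = 0.459), and Ndufv1 was the 1 member that passed when adjusted over the list alone (adjusted p = 0.00277). Of 22 glycolysis genes 15 were positive and 7 negative (camera adjusted p = 0.00561; adjusted p = 0.278 with an estimated correlation). The phosphofructokinase Pfkl was at 4.61 and the isomerase Gpi1 at 2.13 (adjusted p = 0.459 and 0.477). The other probes gave -0.59 and 0.87 for Pfkl and -1.75 for Gpi1. Of 21 hypoxia response genes 17 were positive and 4 negative (camera adjusted p = 0.00332; adjusted p = 0.278 with an estimated correlation). Mxi1, a partner of Max, was at 3.24 and the carbonic anhydrase Car12 at -0.76 (adjusted p = 0.477 and 0.471). Of 30 genes of iron and oxidative stress 22 were positive and 8 negative (camera adjusted p = 0.00101; adjusted p = 0.278 with an estimated correlation). Catalase (Cat) was at 3.44 and the NADPH oxidase subunit Ncf1 at -0.76, and the metal transporter Slc11a1 at 2.26 (each adjusted p = 0.459). No member of the glycolysis, hypoxia and iron lists passed when adjusted over the list alone. Over all settings the adjusted p ranged from 4.4e-10 to 0.744 for oxidative phosphorylation, 7.33e-05 to 0.797 for glycolysis, 0.000186 to 0.744 for hypoxia response and 1.59e-05 to 0.744 for iron and oxidative stress. Without knockout replicate 7 it was 0.155 for glycolysis, 0.119 for hypoxia response and 0.155 for iron and oxidative stress, and without wild-type replicate 1 it was 0.0546 for glycolysis.

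Lists of lipid handling and of uptake and degradation followed. Of 31 genes of lipid uptake and efflux 21 were positive and 10 negative (camera adjusted p = 0.00332; adjusted p = 0.278 with an estimated correlation). Mylip, which targets the LDL receptor for degradation, was at 3.98 and the acetyl-CoA acetyltransferase Acat1 at -0.81 (both adjusted p = 0.459). Of 23 cholesterol biosynthesis genes 13 were positive and 10 negative (camera adjusted p = 0.0121; adjusted p = 0.278 with an estimated correlation). Insig1, which restrains sterol synthesis, was at 2.77 and the transcription factor Srebf2 at -0.53 (adjusted p = 0.465 and 0.499). Of 35 lysosome genes 19 were positive and 16 negative (camera adjusted p = 0.0121; adjusted p = 0.52 with an estimated correlation). The glycoprotein Gpnmb was at 1.30 and the cholesterol transporter Npc1 at -1.03 (adjusted p = 0.467 and 0.475), the latter 2.53 from probes named through RefSeq and 0.75 in the mean over its probes. Of 29 genes of phagocytosis and scavenging 16 were positive and 13 negative (camera adjusted p = 0.0407; adjusted p = 0.278 with an estimated correlation). The GTPase Rac2 was at 1.08 (adjusted p = 0.459). The inhibitory receptor Cd300a had a negative difference (adjusted p = 0.459) that was 0.02 in the mean over its probes. No member of these lists passed when adjusted over the list alone. Over all settings the adjusted p ranged from 7.33e-05 to 0.83 for lipid uptake and efflux, 0.00483 to 0.797 for cholesterol biosynthesis, 0.000186 to 0.954 for lysosome and 0.00601 to 0.954 for phagocytosis and scavenging. Without knockout replicate 7 it was 0.155, 0.298, 0.336 and 0.298 in that order. The lysosome call was also lost without wild-type replicates 1 and 2 and knockout replicate 8 (0.252, 0.0545 and 0.112), and the phagocytosis call without wild-type replicates 1, 2 and 4 and knockout replicate 8 (0.0623, 0.205, 0.051 and 0.185).

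Among immune lists, 20 of 29 type I interferon response genes had a positive and 9 a negative difference (camera adjusted p = 0.00101; adjusted p = 0.278 with an estimated correlation). Ifit3, an interferon-induced antiviral gene, differed by 5.45 (SE 1.09, adjusted p = 0.459), passed when adjusted over the list alone (adjusted p = 0.0353), and passed over all genes without wild-type replicate 3 (adjusted p = 0.0225, range 0.0225 to 0.799 over all settings). The RNA sensor Ddx58 differed by 1.76 and the nucleotide kinase Cmpk2 by -0.76 (both adjusted p = 0.459). Of 20 MHC class I presentation genes 14 were positive and 6 negative (camera adjusted p = 0.00629; adjusted p = 0.493 with an estimated correlation). The chaperone Calr was at 1.45 and H2-T22, whose probe also lists H2-T10, at 1.32 (adjusted p = 0.473 and 0.54). Of 24 genes of complement and Fc receptors 12 were positive and 12 negative (camera adjusted p = 0.0483; adjusted p = 0.278 with an estimated correlation). Properdin (Cfp) was at 2.14 and C4b, whose probe also lists C4a, at 3.33 (both adjusted p = 0.459). Of 30 inflammatory activation genes 12 were positive and 18 negative, with a median of -0.17 against a mean of 0.32 and an upward camera test (adjusted p = 0.0483; adjusted p = 0.278 with an estimated correlation). Tnfaip3, which restrains NF-kB signalling, and the formyl peptide receptor Fpr2 differed by 2.40 and 2.58 (both adjusted p = 0.459). Of 30 genes of alternative activation and repair 16 were positive and 14 negative (camera adjusted p = 0.0393; adjusted p = 0.278 with an estimated correlation), while its members of smallest p, the cytokine signalling inhibitor Socs1 and the chemokine Ccl24, were at -1.68 and -0.85 (both adjusted p = 0.459). Apart from Ifit3 no member of these lists passed when adjusted over the list alone. Over all settings the adjusted p ranged from 4.41e-06 to 0.744 for type I interferon response, 0.000159 to 0.97 for MHC class I presentation, 0.0172 to 0.954 for both complement and Fc receptors and inflammatory activation, and 0.019 to 0.954 for alternative activation and repair.

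Calls of these immune lists also rested on single arrays. Without knockout replicate 7 the adjusted p was 0.155 for type I interferon response, 0.236 for MHC class I presentation, 0.298 for complement and Fc receptors, 0.228 for inflammatory activation and 0.236 for alternative activation and repair. The calls other than type I interferon response were lost without wild-type replicate 1 (0.257, 0.306, 0.106 and 0.0716 in that order) and without wild-type replicate 2 (0.0651, 0.0799, 0.0651 and 0.0908). Without wild-type replicate 4 the adjusted p was 0.13 for inflammatory activation and 0.0624 for alternative activation and repair, and without knockout replicate 8 it was 0.0654 for MHC class I presentation, 0.0774 for complement and Fc receptors and 0.237 for inflammatory activation.

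The remaining called function lists were immediate early and dissociation stress genes, cell cycle genes and genes that glycosylate selectin ligands. Of 26 immediate early and dissociation stress genes, which respond within minutes to stimulation or tissue digestion, 16 were positive and 10 negative (camera adjusted p = 0.00407; adjusted p = 0.278 with an estimated correlation). Its members of smallest p, the transcription factors Klf2 and Nr4a2, were at -0.52 and -2.09 (both adjusted p = 0.459). Of 42 cell cycle genes 23 were positive and 19 negative (camera adjusted p = 0.0134; adjusted p = 0.278 with an estimated correlation). The centromeric histone Cenpa was at 3.44, cyclin B2 (Ccnb2) at 1.72, the ribonucleotide reductase subunit Rrm2 at 2.77 and the kinesin Kif23 at -4.96 (each adjusted p = 0.459). At an unadjusted p under 0.05 were 3 of its members higher and 2 lower. Of 15 genes of selectin ligand glycosylation, whose enzymes modify PSGL-1 and other ligands, 10 were positive and 5 negative (camera adjusted p = 0.0472; adjusted p = 0.278 with an estimated correlation), while B3gnt5 and the fucosyltransferase Fut4 were at -0.70 and -0.59 (both adjusted p = 0.459). The sialyltransferase St3gal6 was at 4.28 (other probes -0.75 and 1.31) and the Golgi glycoprotein Glg1 at 1.43 (other probe -0.17), each with the same adjusted p. No member of these lists passed when adjusted over the list alone. Over all settings the adjusted p ranged from 0.000148 to 0.744 for immediate early and dissociation stress, 0.00263 to 0.94 for cell cycle and 0.0101 to 0.876 for selectin ligand glycosylation. Without knockout replicate 7 it was 0.155, 0.236 and 0.332 in that order. The cell cycle call was also lost without wild-type replicate 4 (0.068), and the glycosylation call without wild-type replicates 1, 2 and 3 and knockout replicate 8 (0.0645, 0.0738, 0.102 and 0.0834).

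**Figure D2:**
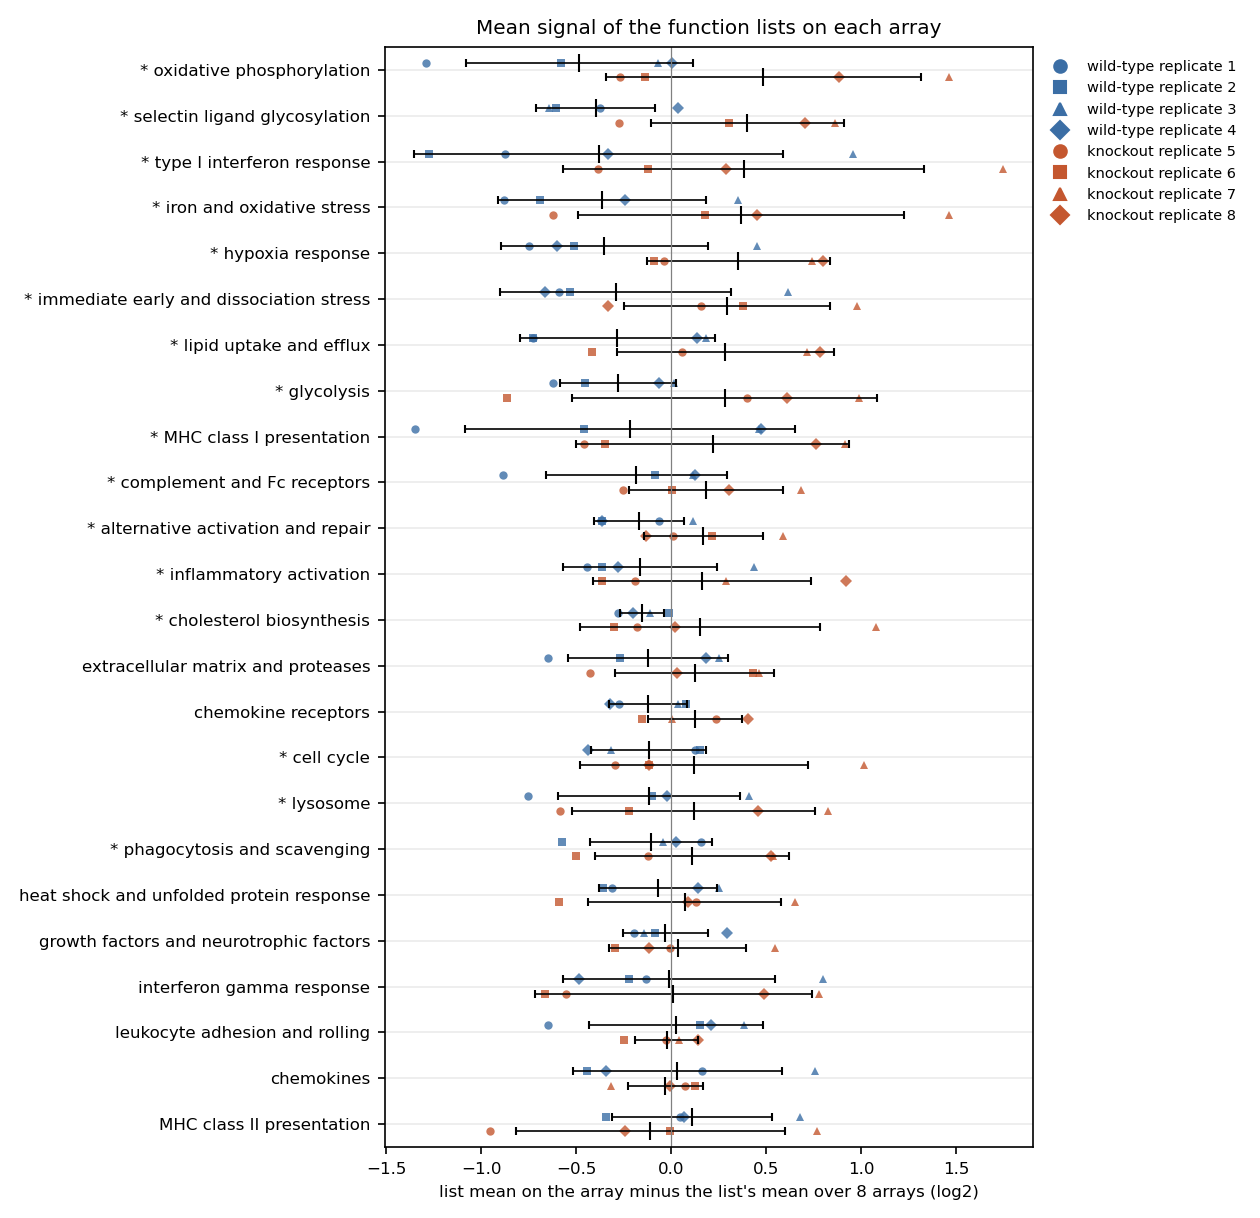
Mean log2 signal of each of the 24 function lists on each array (x axis, relative to the mean of the list over 8 arrays), with 1 point per array (blue wild-type, orange knockout) and black bars at the mean ± SD of 4 arrays; an asterisk marks a camera adjusted p under 0.05. The groups overlap in each of the 16 called lists, as for oxidative phosphorylation, where wild-type arrays reached 9.92 and knockout arrays began at 9.65.

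The other 8 function lists did not pass by camera. Of 26 genes of leukocyte adhesion and rolling, the list closest to PSGL-1 itself, 8 were positive and 18 negative (adjusted p = 0.545), with a median of -0.18 and a mean of -0.05 although camera pointed up relative to the other genes. Its adhesion molecule Pecam1 was at -1.04 (adjusted p = 0.459). Of 21 chemokine receptors 8 were positive and 13 negative (adjusted p = 0.213, median -0.30, mean 0.24, camera up), with the fractalkine receptor Cx3cr1 at -1.30 (adjusted p = 0.459). Of 25 chemokines 8 were positive and 17 negative (adjusted p = 0.87, median -0.43, mean -0.06, camera up), and Cxcl16 at 2.99 (adjusted p = 0.448) passed when adjusted over the list alone (adjusted p = 0.013). Of 25 interferon gamma response genes 14 were positive (adjusted p = 0.172). Of 35 genes of extracellular matrix and proteases 18 were positive (adjusted p = 0.142), with the collagen Col1a2 at -0.86 (adjusted p = 0.459; other probes -1.13 and 0.10). Of 27 genes of heat shock and unfolded protein response 16 were positive (adjusted p = 0.172). Its member Ddit3 was at -0.58 (adjusted p = 0.459) but at 2.81 from probes named through RefSeq and 1.11 in the mean over its probes. MHC class II presentation had 5 of 19 genes positive (adjusted p = 0.904, median -0.23, mean -0.22, camera up), with H2-Ob at -0.58 (adjusted p = 0.459). Growth factors and neurotrophic factors had 13 of 30 positive (adjusted p = 0.465, median -0.09, mean 0.07, camera up), with Tgfb2 at -1.85 (adjusted p = 0.459). Of these lists, 3 passed without single arrays. Interferon gamma response passed without wild-type replicate 3 (adjusted p = 0.0276, range 0.0276 to 0.94 over all settings) and knockout replicates 5 and 6 (0.0438 and 0.0439), heat shock and unfolded protein response without wild-type replicate 3 and knockout replicate 6 (0.0357 and 0.0225, range 0.0225 to 0.94), and extracellular matrix and proteases without wild-type replicate 3 and knockout replicate 5 (0.0205 and 0.0385, range 0.0205 to 0.876). With all arrays, list heat shock and unfolded protein response also passed after quantile normalization (0.0342), with normexp (0.0427) and in the value table (0.0334).

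Cell type lists asked which other cells the sort could hold, but they do not measure how many such cells were present. Some markers of cells outside the sort were brighter in the wild-type arrays than the sort marker gene Itgam (13.61). Examples are the B cell gene Cd79a (14.40) and the neuron gene Syp (14.03), while the B cell gene Cd79b was dimmer (10.02). Brightness was not calibrated between probes, so these values do not compare the amounts of RNA of different genes. Of 16 border-associated macrophage markers 10 were positive and 6 negative (camera adjusted p = 0.0393; adjusted p = 0.278 with an estimated correlation). The transcription factor Maf was at 4.21 (adjusted p = 0.459) and the iron exporter Slc40a1 at -1.53 (adjusted p = 0.461), the latter 1.54 from probes named through RefSeq and 1.41 with normexp. Of 21 Ly6C-high monocyte markers 14 were positive and 7 negative (camera adjusted p = 0.0393; adjusted p = 0.549 with an estimated correlation), while its member Ms4a4c was at -3.81 (adjusted p = 0.459). No member of either list passed when adjusted over the list alone. Over all settings the adjusted p ranged from 0.0154 to 0.821 for border-associated macrophages and from 0.000184 to 0.954 for Ly6C-high monocytes. Without wild-type replicates 1 and 2 and knockout replicates 7 and 8 it was 0.138, 0.0738, 0.228 and 0.0654 for border-associated macrophages and 0.519, 0.238, 0.217 and 0.149 for Ly6C-high monocytes.

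The other 18 cell type lists did not pass. Microglia markers were positive in 9 of 21 genes (adjusted p = 0.799), Ly6C-low monocytes in 8 of 19 (0.904) and conventional dendritic cells 1 in 7 of 16 (0.545), with the receptor Xcr1 at -0.83. NK cells were positive in 9 of 19 genes (0.93), with granzyme B (Gzmb) at -1.19, endothelial cells in 8 of 18 (1.0) and pericytes and fibroblasts in 9 of 18 (0.698). Camera pointed up relative to the other genes for these 6 lists, while median and mean were negative. Under other scalings camera turned down for Ly6C-low monocytes and endothelial cells (quantile normalization), for endothelial cells (array median) and for pericytes and fibroblasts (normexp), and up for erythroid cells (array median). A negative median, a positive mean and camera up were seen in 4 lists. These were plasmacytoid dendritic cells (6 of 16 positive, adjusted p = 0.18, Tcf4 at 4.10) and neutrophils (9 of 23, 0.454, S100a9 at 4.79). The others were platelets and megakaryocytes (6 of 15, 0.326, F2rl2 at -0.65) and astrocytes (8 of 17, 0.18, Slc4a4 at 1.62, other probes -0.52 and -0.41). Camera, median and mean pointed down for conventional dendritic cells 2 (5 of 20 positive, adjusted p = 0.465), mature migratory dendritic cells (4 of 19, 0.465, Tmem123 at -3.66), T cells (3 of 22, 0.326, Icos at -1.11) and B cells (3 of 17, 0.468, Cd79a at -0.62). They also pointed down for basophils and mast cells (3 of 14, 0.93, Cpa3 at -4.15), erythroid cells (4 of 16, 1.0), neurons (4 of 19, 0.412, Slc17a7 at -0.94) and oligodendrocytes (6 of 18, 0.904). Adjusted over the list alone, Enpp2 of the oligodendrocyte list (1.23, other probes -0.34 and 0.88, adjusted p = 0.0382) and Anpep of the list of pericytes and fibroblasts (3.36, adjusted p = 0.0195) passed. Neither passed over all genes (both 0.459), and membership of a list does not show which cells the RNA came from. Conventional dendritic cells 2 were the 1 list of 44 whose arrays did not overlap, at 8.36 ± 0.35 (SD, n = 4) in the wild-type and 7.82 ± 0.04 (SD, n = 4) in the knockout arrays, where chance gives 2.86% of lists. This was read only under the scaling to the 75th percentile, where the median difference of all genes was -0.33. Under that scaling 4550 genes were also lower without overlap, so the separation may depend on the scaling.

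**Figure D3:**
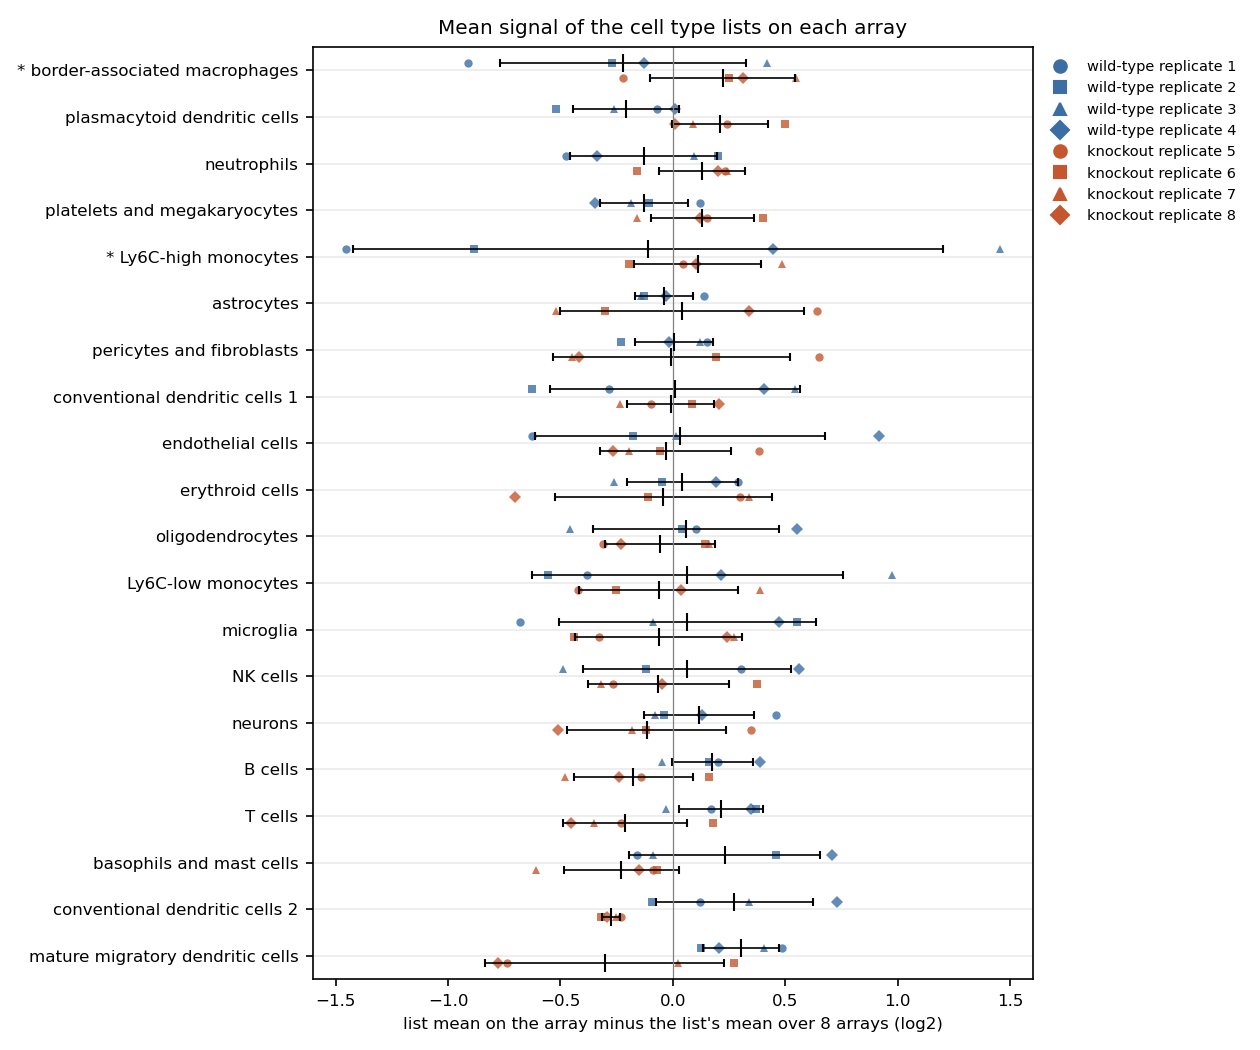
Mean log2 signal of each of the 20 cell type lists on each array (x axis, relative to the mean of the list over 8 arrays), with 1 point per array (blue wild-type, orange knockout) and black bars at the mean ± SD of 4 arrays; an asterisk marks a camera adjusted p under 0.05. The wild-type arrays spread more widely than the knockout arrays for Ly6C-high monocytes (SD 1.31 and 0.28), and under the scaling drawn the groups do not overlap for conventional dendritic cells 2.

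Genes of the sort markers, chosen after the values were seen, did not differ past the threshold. Itgam (CD11b) had a log2 signal of 13.61 ± 0.47 (SD, n = 4) in the wild-type and 13.52 ± 0.97 (SD, n = 4) in the knockout arrays (limma adjusted p = 0.949), and its difference was positive after quantile normalization (0.18) and cyclic loess (0.27). Ptprc (CD45) ranged from 8.65 to 13.89 in the wild-type and from 8.88 to 13.04 in the knockout arrays (limma adjusted p = 0.959), with a difference of -0.22 that was 0.05 after quantile normalization and from -2.97 to 0.51 over its 3 other probes. Ly6g, the neutrophil marker excluded in the sort, was at 6.30 ± 2.77 (SD, n = 4) and 8.70 ± 2.08 (SD, n = 4), with limma adjusted p = 0.528. Of the CD3 genes, also excluded in the sort, Cd3d differed by -0.11, Cd3e by -1.81 and Cd3g by -0.51, and Cd3e was at 12.04 on wild-type replicate 3 against 6.25 to 6.48 on the other wild-type arrays. Without knockout replicate 8 the difference of Cd3d was 0.04, and Itgam and Ptprc also changed sign without single arrays (Itgam 0.10 without wild-type replicate 2 and 0.34 without knockout replicate 5; Ptprc 0.55 and 0.66 without wild-type replicates 3 and 4 and 0.30 and 0.49 without knockout replicates 5 and 8).

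Genes next to Selplg on chromosome 5 can differ between donors through the genetic background of the targeted locus. Of 32 listed neighbours 31 were tested, 12 with a positive and 19 with a negative difference, and 0 passed the limma threshold over all genes (smallest adjusted p = 0.459). At an unadjusted p under 0.05 were 3, Hps4 of a lysosome-related organelle complex (4.19, but -0.78 from its other probe), Wscd2 (-0.57, but 0.23 in the mean over its probes) and the crystallin gene Crybb1 (-0.52). Fisher's exact test of their share against that of all other genes gave p = 1 (two-sided).

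**Figure D4:**
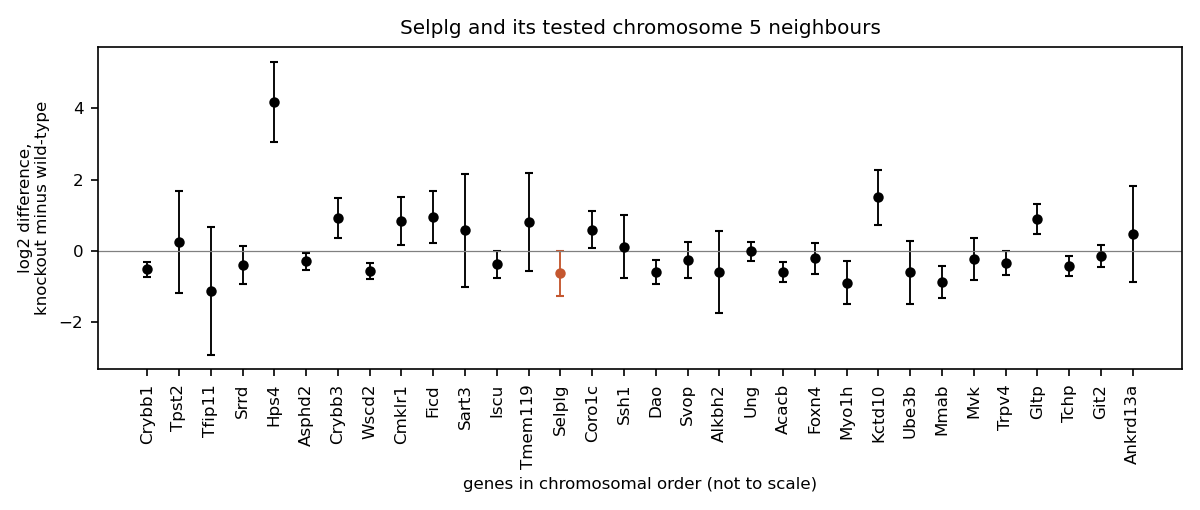
Log2 difference (y axis, knockout minus wild-type) of Selplg, in orange, and its 31 tested chromosome 5 neighbours, in black, in chromosomal order and not to scale, with error bars of 1 SE. The difference of Hps4 is 4.19 from the probe drawn and -0.78 from its other probe, and no neighbour passed the adjusted threshold.

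Sex-linked genes were read because the labels do not give the sex of the donors. The Y-linked Kdm5d was at 14.70 ± 0.17 (SD, n = 4) in the wild-type and 14.25 ± 0.16 (SD, n = 4) in the knockout arrays (exact permutation test, two-sided, p = 0.029, adjusted over 5 genes 0.143). This is the smallest p that 4 arrays against 4 allow, and the difference was positive from probes named through RefSeq (0.51) and in the mean over its probes (0.09). Ddx3y was at 3.05 ± 2.72 and 8.79 ± 1.65 (exact p = 0.057), Uty at 7.69 ± 0.34 and 7.27 ± 0.22 (exact p = 0.086), Eif2s3y at 12.07 ± 1.64 and 12.54 ± 0.79 (exact p = 0.629) and the X-linked Xist at 5.09 ± 0.89 and 4.41 ± 0.76 (exact p = 0.314). Without wild-type replicate 4 the difference of Eif2s3y was -0.13. After quantile normalization 0 of the 5 genes had an exact p under 0.05, and no adjusted exact p was below 0.143.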

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

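Of the tests in this part, both comparisons with random lists matched on mean signal were chosen after the called lists were seen, and the one among protein-coding genes after the outcome of the other. A sample was set apart where its gap to the nearest array of its group was large against the range of the group by Dixon's test. This held in 17 of 292 groups tested, and chance flags about 1 in 20 groups, so the number is close to what chance gives.

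Among named genes, 12 of 198 groups held such an array. Fam169a was at 7.23 on knockout replicate 8 against 5.27 to 5.54 on the other knockout arrays, and the olfactory receptor Olfr1349 at 3.74 on knockout replicate 6 against 3.26 to 3.30. The interferon-induced Ifit3 was at 10.93 on wild-type replicate 3 against 6.02 to 6.68, the chaperone Calr at 13.05 on knockout replicate 7 against 10.67 to 10.75, and cyclin B2 (Ccnb2) at 9.72 on wild-type replicate 1 against 8.14 to 8.29. Glg1 was at 10.87 on wild-type replicate 2 against 8.43 to 8.67, Rrm2 at 13.07 on knockout replicate 7 against 8.80 to 9.30, and Kif23 at 6.67 on knockout replicate 5 against 2.52 to 3.17. The T cell gene Cd3e was at 12.04 on wild-type replicate 3 against 6.25 to 6.48. Of the sex-linked genes, Xist was at 6.43 on wild-type replicate 4 (others 4.59 to 4.71), Ddx3y at 7.10 on wild-type replicate 3 (others 1.38 to 2.11) and Uty at 7.60 on knockout replicate 7 (others 7.11 to 7.19).

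Among list means, 4 of 88 groups held such an array. The cell cycle mean was 9.63 on knockout replicate 7 against 8.32 to 8.50 on the other knockout arrays, and the immediate early and dissociation stress mean 10.67 on wild-type replicate 3 against 9.39 to 9.52 on the other wild-type arrays. The neutrophil mean was 8.23 on knockout replicate 6 against 8.59 to 8.63, and the mean of basophils and mast cells 8.49 on knockout replicate 7 against 8.95 to 9.03. The median processed signal before scaling was 126.5 on knockout replicate 7 against 155.5 to 160.2 on the other knockout arrays.

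The 18 lists that lay higher in the knockout arrays by camera are the pattern a biologist would follow up first. A shift that follows signal is argued against. Of the 18, 17 had a median in the upper 2.5% of 10000 random lists matched on mean signal. A difference between annotated protein-coding genes and other probes is argued against too, since 15 did among protein-coding genes matched in the same way. The 18 were picked for lying above other genes of these arrays, so these comparisons speak only to signal and annotation. They do not set the 18 apart, since lists not called also reached the upper 2.5%. Examples are extracellular matrix and proteases and heat shock and unfolded protein response. Chance cannot be excluded, because 4 of the 35 splits of the 8 arrays into 4 and 4 gave 18 lists or more, the real split included, and the highest other split gave 24 lists with wild-type replicates 1, 2 and 4 and knockout replicate 5 on one side. A structure of the samples that follows single arrays stays open, as leaving out knockout replicate 7 kept 1 of the 18 lists. An effect of donor PSGL-1 stays open, as untested, and cannot be told apart from the slide columns.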

How the results depend on the processing

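The settings limited to probes named through RefSeq, to the brighter part of the genes, to cyclic loess and to the arrays without knockout replicates 7 and 8 were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Of the comparisons of a named gene with its alternatives, 2036 kept direction and side of the threshold, 22 passed only in the alternative, 3 were lost and 32 reversed, and for lists 843 kept both, 10 passed only in the alternative, 168 were lost and 79 reversed. The cause was not tested unless said. Signal over background limited the dim genes, of which only Ncbp2 was read as a bound.

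Leaving out single arrays moved the Selplg difference from -1.01 to 0.01, changed genes from 0 to 10, higher genes from 0 to 10, lower genes from 0 to 2, chromosome 5 neighbours from 0 to 0 and lists past the threshold from 1 to 20. Differences that changed sign ranged from -0.37 to 0.34 for gene Itgam, -1.09 to 0.66 for gene Ptprc, -0.29 to 0.04 for gene Cd3d and -0.13 to 1.17 for gene Eif2s3y. For lists, whose values are the mean against all other genes, camera turned direction within -0.09 to 0.29 for list leukocyte adhesion and rolling, -0.36 to 0.26 for list MHC class II presentation, -0.19 to 0.23 for list microglia, -0.14 to 0.39 for list Ly6C-low monocytes, -0.06 to 0.31 for list erythroid cells, -0.10 to 0.37 for list endothelial cells, -0.04 to 0.40 for list chemokines, -0.41 to -0.16 for list basophils and mast cells, -0.10 to 0.18 for list NK cells, -0.08 to 0.19 for list oligodendrocytes and -0.03 to 0.31 for list pericytes and fibroblasts. Without knockout replicates 7 and 8 changed genes and higher genes were 0 (1802 at an unadjusted p under 0.05) and lists past the threshold 0 (1 unadjusted). Camera then turned for list chemokines (0.20), list interferon gamma response (-0.46), list MHC class II presentation (-0.46), list MHC class I presentation (-0.06), list lysosome (-0.15), list heat shock and unfolded protein response (-0.03), list growth factors and neurotrophic factors (0.01), list microglia (-0.32), list Ly6C-low monocytes (-0.27), list basophils and mast cells (-0.18) and list erythroid cells (0.18).

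Among scalings, quantile normalization gave 0 sex-linked genes with an exact p under 0.05 and turned gene Itgam (0.18), gene Ptprc (0.05), list Ly6C-low monocytes (0.00) and list endothelial cells (0.08). Scaling to the median gave 11 lists past the threshold and turned gene Itgam (0.05), gene Cd3d (0.04), list erythroid cells (0.10) and list endothelial cells (0.12). Normexp turned gene Slc40a1 (1.41), gene Itgam (0.17), list Ly6C-low monocytes (-0.04), list endothelial cells (0.08) and list pericytes and fibroblasts (0.12). The value table turned gene Ddit3 (0.00), gene Itgam (0.19), gene Ptprc (0.06), list Ly6C-low monocytes (-0.05) and list endothelial cells (0.08). Cyclic loess gave 4 changed genes and 4 higher genes, 10 lists past the threshold, and turned gene Itgam (0.27), gene Ptprc (0.01), gene Cd3d (0.16), list Ly6C-low monocytes (0.01) and list endothelial cells (0.07). Array weights turned gene Ptprc (0.35). The slide row as a block gave 2 changed genes and 2 higher genes, and turned list erythroid cells (0.10). Some of these lists turned without a change in the sign of the mean, since camera weighs each gene by its spread.

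Among filters, requiring all 8 arrays above background gave 7 changed genes, 5 higher genes and 2 lower genes, and turned list basophils and mast cells (0.03) and list erythroid cells (0.16). With no filter list endothelial cells turned (-0.03). The brighter genes alone gave 8 changed genes, 7 higher genes and 1 lower gene (lower genes 1), 8 lists past the threshold, and turned list NK cells (-0.22), list oligodendrocytes (0.10) and list pericytes and fibroblasts (-0.10). All 8 arrays above background (35006 genes) and the brighter genes (21156) leave fewer tested genes to adjust over than the 42312. Probes named through RefSeq gave 12 changed genes, 10 higher genes and 2 lower genes, 11 lists past the threshold, and turned gene Zfp945 (1.04), gene Npc1 (2.53), gene Ddit3 (2.81), gene Slc40a1 (1.54), gene Kdm5d (0.51), list Ly6C-low monocytes (-0.01), list NK cells (-0.08) and list endothelial cells (-0.14). The mean over all probes gave 5 changed genes and 5 higher genes, and turned gene Cd300a (0.02), gene Npc1 (0.75), gene Ddit3 (1.11), gene Slc40a1 (0.00), gene Wscd2 (0.23), gene Kdm5d (0.09), list Ly6C-low monocytes (0.02) and list endothelial cells (0.11). Both settings read other probes, which is how they change these genes. An adjusted p under 0.1 gave 14 changed genes, 11 higher genes and 3 lower genes.

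For set tests, an estimated correlation and fry each gave 0 lists past the threshold (6 and 5 unadjusted), and lists without shared genes gave 10 and turned list growth factors and neurotrophic factors (0.11). Fry, which compares a list with 0 and not with other genes, turned 19 lists, which its construction allows given the shift of all genes, at means of -0.05 for list leukocyte adhesion and rolling, 0.24 for list chemokine receptors, -0.06 for list chemokines, 0.32 for list inflammatory activation, 0.02 for list interferon gamma response, -0.22 for list MHC class II presentation, 0.24 for list extracellular matrix and proteases, 0.14 for list heat shock and unfolded protein response, 0.07 for list growth factors and neurotrophic factors, -0.13 for list microglia, -0.13 for list Ly6C-low monocytes, -0.02 for list conventional dendritic cells 1, 0.42 for list plasmacytoid dendritic cells, 0.26 for list neutrophils, -0.13 for list NK cells, 0.26 for list platelets and megakaryocytes, 0.08 for list astrocytes, -0.07 for list endothelial cells and -0.01 for list pericytes and fibroblasts.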

Other observations

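Of the tests in this part, the scaling test, the splits under other scalings and by slide row, the tests of 2 probes of a gene and of cell mixtures, and the gene list correlations between arrays were chosen after the result was seen, and the brightest 5% of probe pairs were set apart after several cutoffs of brightness had been looked at.

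Genes of 5 of the 44 lists varied together between arrays of a group, with a mean correlation in the upper 2.5% of 1000 random lists matched on mean signal. These were MHC class I presentation (0.349), Ly6C-high monocytes (0.24), oxidative phosphorylation (0.194), type I interferon response (0.139) and iron and oxidative stress (0.116). Type I interferon genes averaged 9.97 on wild-type replicate 3 and 10.76 on knockout replicate 7, against 7.74 to 8.68 on the other wild-type and 8.63 to 9.30 on the other knockout arrays. Ly6C-high monocyte markers averaged 11.86 on wild-type replicate 3 and 8.95 on wild-type replicate 1, a spread within wild-type arrays that exceeded the group difference of 0.22.

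Over all tested genes, the first principal component held 20.6% of the variance and ran from knockout replicates 7 (237.5) and 8 (123.5) to wild-type replicates 1 (-132.4) and 4 (-144.9). The second held 15.2% and set wild-type replicate 4 apart (240.1). Neither component separated the groups. Differences of 2 probes of a gene between the groups correlated at 0.17 (Pearson, across genes, which are not independent replicates) and 0.11 (Spearman).

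The spread between arrays of a group was wide, with a median SD of 0.76 (quartiles 0.42 and 1.49, log2), and 25.6% of genes ranged over more than 16-fold within a group. Noise of single spots is argued against, since the SD between spots of a probe on an array (0.072) was 0.077 times that between arrays (0.93) for the same probes. Different mixtures of cell types in the samples stay open, since 1 of the 20 cell type lists, Ly6C-high monocytes, was above the bound on gene list correlation, in a test that decides nothing where even 2 probes of a gene barely correlate. Different gene levels in the samples stay open. Over 3135 genes, 2 probes of a gene correlated within groups at a median of 0.11, close to the 0.02 of probes of different genes. This cannot decide the question, since it would also arise where 1 of the 2 probes does not read the gene. For 16 genes with both probes among the brightest 5%, the median was 0.75. Few RNA molecules or cells per sample stay open, since the brightest 5% of genes had an SD of 0.32, which is 0.417 of that of all genes, but the median SD in 4 equal classes of signal, from the dimmest, was 0.80, 0.84, 0.85 and 0.59, so the spread did not rise further toward the dimmest genes.

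For single genes, chance cannot be excluded for the 1 gene past the adjusted threshold, because 20 of 35 splits gave at least 1, and the highest other split gave 13. Under the scaling to the 75th percentile, only the real split, 1 of 35, gave as many as 4571 genes at an unadjusted p under 0.05. The highest other split gave 3455. This is the smallest share that 35 splits allow, and the 75th percentile itself separated the groups before scaling, so chance is not excluded. The 18 splits that keep the slide rows balanced are too few for a share under 5% (the split by row gave 1266). Under most other scalings chance cannot be excluded either. As many came from 5 of 35 splits after cyclic loess, against 1 after scaling to the array median. Such genes were as many in 2 splits after quantile normalization, 3 with normexp and 2 in the value table. Their excess may come from the scaling of arrays that differed in the 75th percentile of signal between the groups, since 4.8% of genes had an unadjusted p under 0.05 after cyclic loess against 10.8% before, where chance gives 5%, and 6.4% to 6.6% after the other 4 scalings. An effect of donor PSGL-1 and the slide columns stay open and cannot be told apart.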
